A study of Homo sapiens with 12 samples.

How the data were processed

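The series holds 12 RNA sequencing libraries from HEK293, a human embryonic kidney cell line. The cultures received vehicle, oleic acid, ferric ammonium citrate (FAC, an iron salt) or oleic acid together with FAC, with 3 replicates each. Per the labels, total RNA had an integrity number of 10 in all samples and was made into libraries by poly-A selection and Illumina TruSeq chemistry. The doses and the length of treatment are not given in the sources used here. The labels number the replicates and do not say whether they were separate cultures.

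The processing notes name bcl2fastq 2.19, kallisto 0.46.1, sleuth 0.30.0 and the human build GRCh38.p12 (hg38). Per the labels, the deposited tables hold estimated counts from kallisto, 1 table per gene symbol and 1 per transcript. The values in both tables were already whole numbers, so rounding changed none of them. The gene table has 36459 symbols, of which 21909 have a count in some library, and the transcript table has 188753 transcripts. For 97.0% of the 35266 genes compared, the gene value equalled the sum of its transcripts within 5 counts. The sleuth output was not used here. Gene coordinates, gene types and transcript lengths came from GENCODE 29 on the same build, in which 97.0% of the gene symbols were found.

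Library totals ran from 14098216 to 18717397 counts. A count of 0 allows up to 3 counts, which is 0.160 to 0.213 CPM (counts scaled to a common library total) in a library. Such limits cover counting error only, because the reads carry no molecular identifiers. Within groups, every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom from 8.14 to 122.19.

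Genes were kept by the filterByExpr function of edgeR 4.0.16 at its default settings, which left 14209 genes and 51464 transcripts. Libraries were scaled by trimmed mean of M values (TMM). All 12 libraries entered 1 quasi-likelihood fit in edgeR (R 4.3.3), with a mean for each group, and 5 contrasts between groups and the interaction of oleic acid and FAC were tested by two-sided F tests. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05. Levels are given as CPM scaled by TMM, as mean ± SD over 3 libraries.

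Fixed gene lists, 31 in number, cover pathways, complexes, stress responses and markers of other cell types. The 26 pathway and stress lists were tested against all other genes with camera in limma 3.58.1, at a preset correlation of 0.01 between genes, and adjusted over the lists within a comparison. Each was tested again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Counts of members past the test are given over all genes and adjusted over the list alone.

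The FAC effect with oleic acid was set against the FAC effect without it as a slope through 0 across the genes called without it. Overlaps between comparisons that share libraries were set against 30 simulations of unchanged groups. These were drawn at the library sizes of the data, with a common spread per gene for all groups. With 3 libraries in each control group, the controls could not be divided between comparisons.

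The comparisons, tests, lists, named genes and most alternatives were chosen before the data were examined. Named genes had to pass the test, have a mean log2 CPM of at least 1 and show no overlap between the replicates of the groups compared. From these were taken the 8 highest and 8 lowest fold changes in FAC against vehicle, oleic acid against vehicle and oleic acid + FAC against FAC, and the 4 highest and 4 lowest elsewhere. A fixed set of iron, ferroptosis and fatty acid genes was named whatever its result. For each list past camera, or with at least 3 members past the gene test, up to 4 members past the gene test with the largest changes were added, and for each marker list its most abundant member. Some genes that this rule names are not reported here.

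The steps were tested on simulated counts for all 12 libraries, with gene means, spreads and library sizes taken from the fit of all 12. Changed genes were drawn from those with a mean of at least 2 CPM, so lower genes were not tested. The recovered shares are for FAC against vehicle. With 14066 genes kept, edgeR recovered 14.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 97.0% of those changed 4-fold, and 8.63% of its calls were unchanged genes. The values were 17.9%, 70.1%, 97.0% and 8.45% for limma-voom, and 34.3%, 79.1%, 100% and 17.2% for DESeq2 1.42.0. A planted list gave a camera adjusted p of 4.3e-21 and 0 of 30 random lists were called. Genes were drawn independently of each other here. The list result therefore does not test how often camera calls lists whose genes move together by chance. For a simulated slope of 0.5, the slope over all called genes came to 0.34, below the simulated value. Restricting it to genes with a mean log2 CPM of at least 1 gave 0.50, and selecting genes in the other comparison gave 0.54. The restricted slope was added after this was seen and is given beside the planned one.

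Whether replicate numbers pair the libraries was checked by correlating the deviations from group means of same-numbered libraries. Every replicate gave a correlation over 0.1 in oleic acid + FAC against FAC (0.23, 0.22 and 0.34) and in oleic acid + FAC against oleic acid (0.46, 0.30 and 0.61), and between the FAC and the oleic acid libraries (0.17, 0.26 and 0.33), but not in the comparisons against vehicle. Same-numbered libraries can also correlate through a shared trend with transcript length, and differently numbered libraries were not compared. The correlations therefore do not show pairing by culture. Because pairing is possible, values from a fit with the replicate number as a block are given beside results in those comparisons and the interaction where they differ.

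The alternatives were relative log expression size factors, DESeq2, limma-voom, no expression filter beyond 1 count, a filter of at least 1 CPM in at least 3 libraries, the replicate block, a fit of only the groups compared, and leaving out each library in turn. DESeq2 was run without the edgeR filter, on the 21909 genes with a count, so its counts differ in tool and in gene set. Another 3 settings were added after seeing the data. They leave out the third oleic acid and the third oleic acid + FAC libraries together, remove a trend with transcript length from each library, or combine that removal with the replicate block. Leaving out libraries was also added for the transcripts. The deposited tables have no bootstraps, so the uncertainty of assigning reads between transcripts is not part of the transcript tests.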

Results

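Gene expression was measured by poly-A RNA sequencing in HEK293 cells given vehicle, oleic acid, FAC or oleic acid + FAC, with 3 libraries in each group. The series describes FAC as the inducer of ferroptosis, a form of cell death driven by iron and lipid peroxidation, and its title concerns the inhibition of ferroptosis by oleic acid, a monounsaturated fatty acid. Library totals ran from 14098216 to 18717397 counts, and 14209 genes were tested. The p-values measure only the spread between these libraries.

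On the second principal component (16.1% of the variance) the 6 libraries without FAC scored 11.6 to 30.6 and the 6 with FAC scored -20.6 to -7.46. The first component (32.8%) set the third oleic acid library (40.8) and the third oleic acid + FAC library (62.0) apart from the other 10, which scored -24.7 to 9.69. In both of these libraries short transcripts were relatively high: across genes, which are not independent replicates, the deviation from the group mean correlated with log2 transcript length at -0.71 and -0.54. The trend is not theirs alone: the first vehicle and the third FAC library had -0.44 each, and the other 8 had -0.037 to 0.60. The third oleic acid + FAC library also had 12.1% of its counts on mitochondrially encoded mRNAs, against 3.33% to 7.50% in the other libraries.

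**Figure D1:**
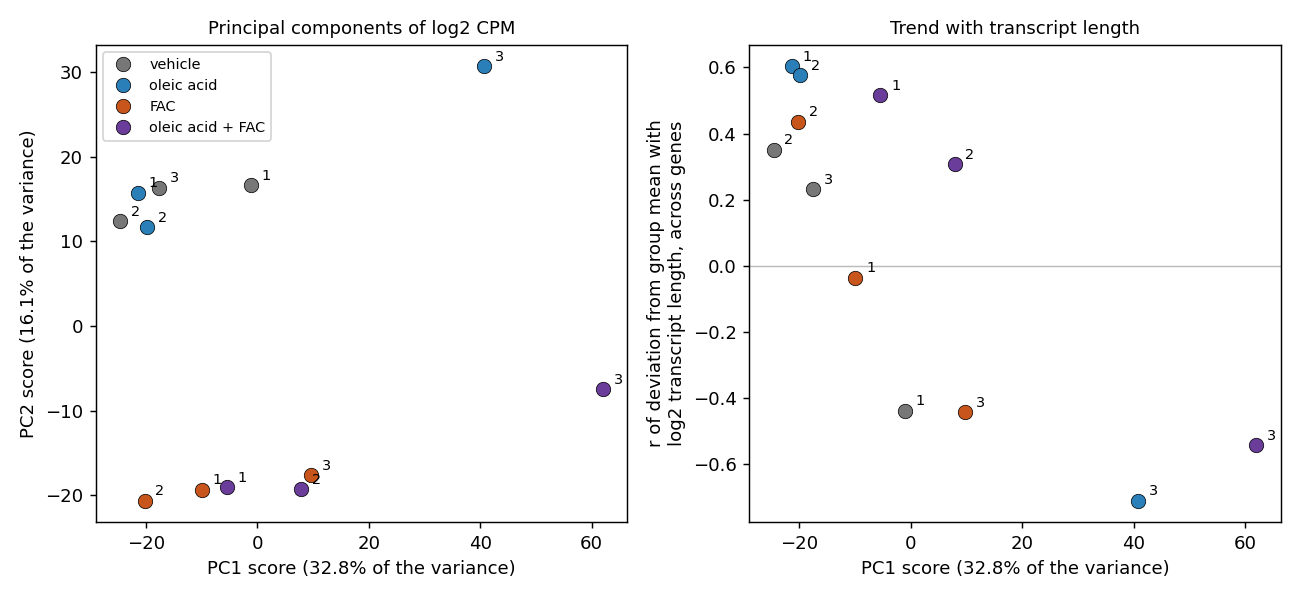
Left, principal component scores of the 12 libraries from log2 CPM, with the replicate number beside each point; right, the first score against the correlation across genes between a library's deviation from its group mean and log2 transcript length. The third oleic acid and the third oleic acid + FAC libraries lie at 40.8 and 62.0 on the first component, to the right of the other 10.

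The most abundant marker of each other cell type measured 0.095 to 15.6 CPM in the vehicle libraries. These were COL1A1 for fibroblasts (15.6 ± 1.95 CPM, n = 3), EPCAM for epithelium in general (7.75 ± 2.84) and ESAM for endothelium (0.99 ± 0.44). HBA1 stood for blood cells (0.58 ± 0.57) and APOA1 for hepatocytes (0.095 ± 0.061), the last below the 3-count floor. In the oleic acid + FAC libraries the same genes stood at 14.8 ± 3.30, 11.2 ± 1.21, 0.61 ± 0.075, 0.95 ± 0.60 and 0.15 ± 0.13 CPM.

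FAC against vehicle asks what FAC alone does to these cells. No group received ammonium or citrate without iron, so effects of iron and of the other parts of the salt cannot be told apart. TFRC, the transferrin receptor that imports iron, fell from 122 ± 10.6 to 19.5 ± 2.62 CPM (SD, n = 3), a log2 fold change of -2.64 (SE 0.25, adjusted p = 2.3e-04). MAT2A, which makes the methyl donor S-adenosylmethionine, fell from 236 ± 40.5 to 65.8 ± 18.6 CPM (-1.84, SE 0.21, adjusted p = 0.00121). INSIG1, a sterol-sensing regulator of cholesterol synthesis, rose from 79.1 ± 17.2 to 418 ± 54.8 CPM (2.40, SE 0.20, adjusted p = 1.8e-04). On GRCh38, TFRC lies on chromosome 3 at 196027183 to 196082189, MAT2A on chromosome 2 at 85539165 to 85545280 and INSIG1 on chromosome 7 at 155297776 to 155310235, and all are annotated as protein-coding genes.

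Among 14209 genes, 169 changed, 65 up and 104 down, with 26 up and 23 down at least 2-fold. Other large rises were those of HIST2H2BE (log2 fold change 2.24), ZC3H6 (1.85), the immediate-early transcription factor EGR1 (1.71), HIST2H4B (1.63), LNP1 (1.52) and the sterol synthesis enzyme MSMO1 (1.504), with adjusted p from 4.7e-04 to 0.0192. Other large falls were those of the chemokine CXCL8 (-1.94), ZNF365 (-1.66), FAM187A (-1.60), FAM13B (-1.50), the proline synthesis enzyme PYCR3 (-1.43) and ZNF587B (-1.39), with adjusted p from 1.9e-04 to 0.0283. The histone genes HIST2H2BE and HIST2H4B have near-identical copies, so reads may not be assigned to the right copy.

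Genes of cholesterol metabolism rose together. Of 25 tested, 7 rose over all genes and 10 adjusted over the list alone, and none fell by either count. The list had a median log2 fold change of 0.28 and a camera adjusted p of 4.2e-20, with an adjusted p = 0.00807 with an estimated correlation. Besides INSIG1 and MSMO1 they included IDI1, an enzyme of isoprenoid synthesis (1.27, adjusted p = 0.00961), SQLE (1.03) and HMGCS1 (0.78). Of 24 immediate-early genes, which respond quickly to many stimuli, 3 rose over all genes and 10 adjusted over the list alone: EGR1, KLF6 (0.76, adjusted p = 0.0182) and MYC (0.60, adjusted p = 0.0213) were the 3. That list had a median of 0.36 and a camera adjusted p of 1.4e-11, with an adjusted p = 0.107 with an estimated correlation.

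Of 12 ferroptosis markers, 1 fell over all genes (TFRC) and 2 fell adjusted over the list alone (TFRC and CHAC1). The list had a median of -0.30 and a camera adjusted p of 4.9e-04, with an adjusted p = 0.0478 with an estimated correlation. TFRC mRNA is degraded in iron-replete cells through its iron-responsive elements, and CHAC1 is a glutathione-degrading enzyme induced by amino acid stress. The 60 nuclear genes of oxidative phosphorylation had a median of 0.14 and a camera adjusted p of 0.0175, with 0 members past the gene test (edgeR) and an adjusted p = 0.781 with an estimated correlation. It did not pass without the second (adjusted p = 0.151) or the third vehicle library (0.118) or the third FAC library (0.547). In the other 22 lists camera did not pass. They gave adjusted p from 0.137, for heat shock proteins, to 0.973, for mitochondrially encoded mRNAs. With the replicate block 5 lists passed camera instead of 4.

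The fixed ferroptosis genes other than TFRC did not pass. The ferritin subunits FTH1 and FTL, which store iron, had log2 fold changes of 0.25 (adjusted p = 0.672) and 0.28 (0.781), and the iron exporter SLC40A1 had -1.18 (0.115). GPX4, which reduces lipid peroxides, had 0.19 (0.805), the cystine importer SLC7A11 -0.56 (0.293), ACSL4, which activates polyunsaturated fatty acids, 0.24 (0.640), and AIFM2 -0.07 (0.961). HMOX1, which degrades heme, had 0.28 (0.880), CHAC1 -1.48 (0.0760) and PTGS2 -0.73 (0.586). Of 14 alternatives each, SLC40A1 passed in 3 (adjusted p from 0.0119 to 0.343 over the 14): DESeq2, the replicate block and without the third oleic acid and the third oleic acid + FAC libraries. CHAC1 passed in 5 (0.00726 to 0.279), which were these, the length trend removed and no filter, and SLC7A11 in 2 (0.0309 to 0.617), without those libraries and with the length trend removed. Each of these 3 genes had a negative fold change in every one of the 14, and none passed with 1 library left out.

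An unadjusted p under 0.05 was found for 1715 genes, where 710 would be reached by chance. Leaving out 1 library gave 79 genes without the first, 33 without the second and 27 without the third vehicle library, and 37, 53 and 37 without the first, second and the third FAC libraries. INSIG1, HIST2H2BE, EGR1, LNP1, MSMO1, TFRC, CXCL8, MAT2A and PYCR3 passed in each of these fits, whereas ZC3H6 did not without the third vehicle library (adjusted p = 0.0675) and IDI1 not without the second (0.0626). HIST2H4B, FAM187A and ZNF587B passed only without the first vehicle library (0.0556 to 0.146 elsewhere), ZNF365 only without the second (0.0593 to 0.109 elsewhere), FAM13B only without the first vehicle or the second FAC library (0.0735 to 0.0969 elsewhere), and KLF6 and MYC in none of these fits (0.0657 to 0.135). The count was 505 by DESeq2, run on 21909 genes without the edgeR filter, 172 by limma-voom and 351 from these 6 libraries alone. It was 672 without the third oleic acid and the third oleic acid + FAC libraries, which enter through the shared estimate of spread. With the length trend removed it was 464.

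**Figure D2:**
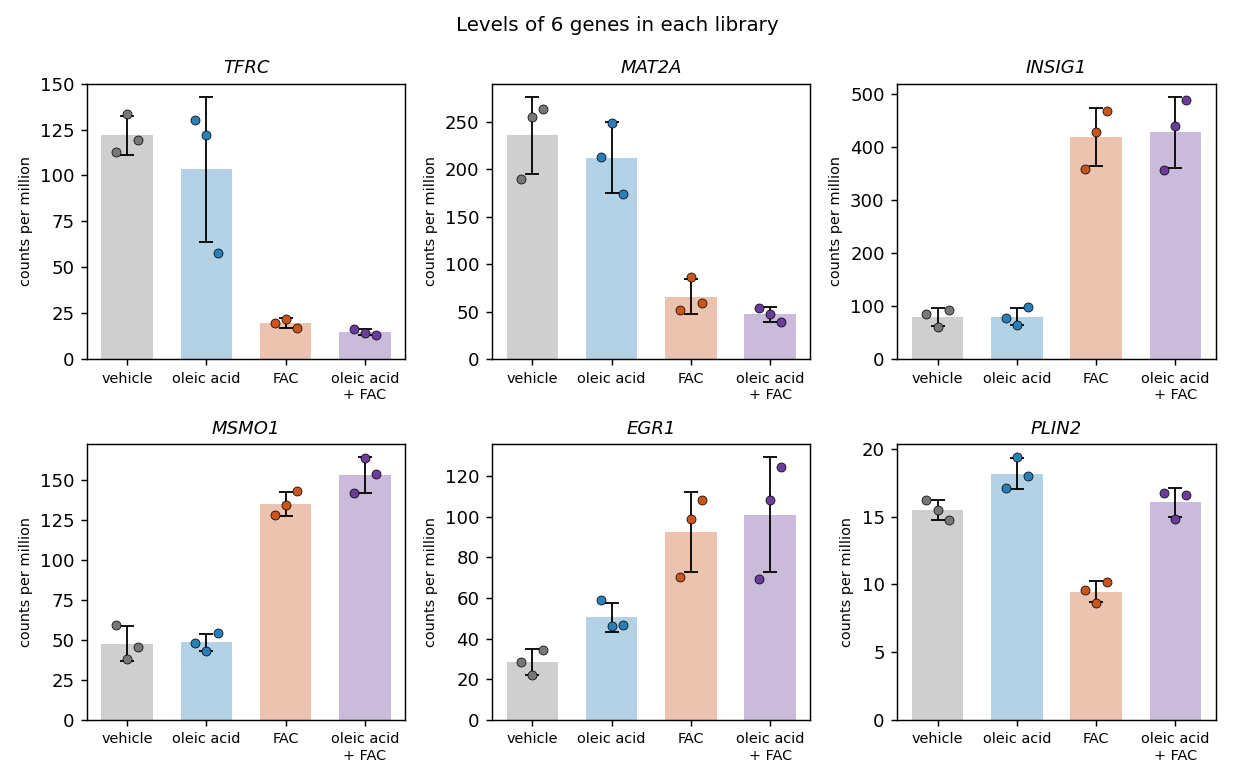
Levels of 6 genes in CPM (TMM-scaled) in each library (points), with the group mean (bar) and SD (error bar, n = 3). TFRC and MAT2A are lower and INSIG1, MSMO1 and EGR1 higher in the FAC groups than in their counterparts without FAC, and PLIN2 stands at 9.47 CPM in FAC and 16.1 CPM in oleic acid + FAC.

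Oleic acid against vehicle asks what the fatty acid does without FAC. CPT1A, which carries fatty acids into mitochondria for oxidation, measured 35.3 ± 6.17 CPM in vehicle and 49.9 ± 8.66 CPM in oleic acid (SD, n = 3), a log2 fold change of 0.50. PDK4, which restrains glucose oxidation, measured 5.04 ± 0.77 and 7.52 ± 1.85 CPM (0.58), and the lipid droplet coat protein PLIN2 15.5 ± 0.74 and 18.2 ± 1.14 CPM (0.23). None of these passed, each with an adjusted p = 1.00. Together, the 15 tested genes that respond to PPAR, the fatty acid-sensing nuclear receptors, were higher: 13 had a positive fold change, the median was 0.20 and the camera adjusted p was 1.6e-04, with an adjusted p = 0.0474 with an estimated correlation.

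No gene changed: edgeR called 0, DESeq2 0 and limma-voom 0, and 118 genes had an unadjusted p under 0.05. That is fewer than the 710 reached by chance, so the p values run conservative here and a count of 0 does not show that no gene changed. The fatty acid synthesis genes SCD (-0.17) and FASN (-0.02), HMGCS1 (0.05) and ACSL3 (-0.04) had an adjusted p = 1.00, and ANGPTL4 was too low to test. In camera, immediate-early genes were higher (median 0.28, adjusted p = 3.0e-08), as were oxidative phosphorylation subunits (0.19, 1.3e-07) and mitochondrially encoded mRNAs (0.31, 0.0165), and p53 targets were lower (-0.10, 0.0177). With an estimated correlation the adjusted p was 0.336 for immediate-early genes and 0.832 for each of the other lists. The third oleic acid library, with its excess of short transcripts, bears on the oxidative phosphorylation list, which was lower rather than higher without that library (adjusted p = 0.0277). The mitochondrially encoded mRNAs did not pass without the first vehicle (adjusted p = 0.585), the second oleic acid (0.228) or the third oleic acid library (0.572), and p53 targets not without the first vehicle (0.585), the third vehicle (0.0660) or the second oleic acid library (0.408). The remaining 21 lists did not pass.

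Oleic acid + FAC against FAC is the comparison the title of the series is about. PLIN2, a lipid droplet coat protein, measured 9.47 ± 0.77 CPM in FAC and 16.1 ± 1.08 CPM in oleic acid + FAC (SD, n = 3), a log2 fold change of 0.76 (SE 0.12, adjusted p = 0.406), named here after its values were seen. Vehicle stood at 15.5 ± 0.74 CPM: FAC alone had lowered PLIN2 (-0.71, adjusted p = 0.0146 in edgeR), and oleic acid + FAC differed from vehicle by 0.05 (adjusted p = 0.827), so oleic acid + FAC stood near the vehicle level rather than above it. The fall with FAC passed in none of the 6 fits with 1 library left out (adjusted p from 0.0518 to 0.0713), and the interaction did not pass (0.53, adjusted p = 1.00). PDK4, likewise chosen after its values were seen, measured 5.08 ± 0.68 and 9.57 ± 1.04 CPM (0.91, adjusted p = 0.707). Neither passed over all genes, but adjusted over the list alone 3 of the 15 PPAR-responsive genes rose, PDK4, PLIN2 and the carnitine carrier SLC25A20 (0.42). Of 29 genes of fatty acid beta-oxidation, 2 rose adjusted over the list alone, ECH1 (0.65) and ACAA2 (0.36), and 0 over all genes.

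Over all genes edgeR called 0 (smallest adjusted p 0.406; 0 with the replicate block), limma-voom called 0 and DESeq2 called 1, PLIN2 (0.76, adjusted p = 0.00140). That is opposite to its fall with FAC, but both comparisons use the FAC libraries, whose chance values alone give opposite signs. With the length trend removed and the replicate block another gene was called, LPCAT1, named here after its values were seen (0.74, adjusted p = 0.00824, against 0.67 and adjusted p = 0.707 in edgeR without these). An unadjusted p under 0.05 was found for 576 genes, and for 1631 with the replicate block, where 710 would be reached by chance. The beta-oxidation list had a median of 0.13 and a camera adjusted p of 2.3e-04, and the PPAR-responsive list 0.15 and 0.00642, with an adjusted p = 0.164 with an estimated correlation for each. Oxidative phosphorylation subunits were higher (median 0.33, adjusted p = 7.3e-13), as were mitochondrially encoded mRNAs (0.80, 2.3e-04), but each had an adjusted p = 0.848 with an estimated correlation. These are the gene groups that moved with the third oleic acid + FAC library, and without it the mitochondrially encoded mRNAs did not pass (adjusted p = 0.837) and the median of the oxidative phosphorylation subunits was 0.14. The 5 tested metallothionein and zinc export genes were higher (0.55, 0.0253; adjusted p = 0.365 with an estimated correlation) and the iron- and 2-oxoglutarate-dependent dioxygenases lower (-0.14, 0.0227; adjusted p = 0.848 with an estimated correlation). The metallothionein list did not pass without the second FAC (adjusted p = 0.108), the first oleic acid + FAC (0.0559) or the third oleic acid + FAC library (0.105), the dioxygenases not without the third FAC (0.112) or the third oleic acid + FAC library (0.361), and the PPAR-responsive genes not without the first oleic acid + FAC library (0.0688).

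The iron and ferroptosis genes did not pass here. TFRC had a log2 fold change of -0.42 (adjusted p = 0.707), FTH1 0.26, FTL 0.40, GPX4 0.32 and CHAC1 0.91 (each 0.707), ACSL4 -0.18 (0.715), SLC40A1 0.23 (0.813), SLC7A11 -0.11 (0.859), AIFM2 0.08 (0.910), PTGS2 0.11 (0.940) and HMOX1 -0.01 (0.993). As edgeR called 0 genes here and 0 for oleic acid against vehicle, overlaps of these calls with the 169 genes changed by FAC could only be 0. Across 12408 genes the fold changes of FAC against vehicle and of oleic acid + FAC against FAC, which share the FAC libraries, correlated at -0.061, where the simulations gave -0.50 from the shared libraries alone. The covariance was -0.0044, against -0.030 simulated. For FAC and oleic acid, each against vehicle, the correlation was 0.17 (0.50 simulated) and the covariance 0.0083 (0.030 simulated). The simulations gave every group the same spread, which fixes these correlations near 0.50 in size. Across genes, deviations from the group mean had an SD of 0.319 in the third oleic acid library. They had 0.317 in the third oleic acid + FAC library and 0.144 to 0.193 in the vehicle and FAC libraries. The gaps to the simulated values are therefore not read as a relation between the effects.

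Oleic acid + FAC against oleic acid asks whether FAC acts in cells given the fatty acid, and shares no library with FAC against vehicle. TFRC fell from 103 ± 39.6 to 14.6 ± 1.58 CPM (log2 fold change -2.83, SE 0.25, adjusted p = 2.1e-04; n = 3), and MAT2A from 212 ± 37.4 to 47.0 ± 7.75 CPM (-2.17, SE 0.22, adjusted p = 3.7e-04). INSIG1 rose from 79.9 ± 16.6 to 428 ± 66.8 CPM (2.42, SE 0.20, adjusted p = 1.7e-04). HIST2H2BE (1.96), ZC3H6 (1.86) and MSMO1 (1.66) also rose and FAM187A (-1.85) and FAM13B (-1.84) fell, with adjusted p from 2.1e-04 to 0.00780. In the third oleic acid library TFRC was at 57.8 CPM, against a mean of 126 in the other two.

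In all 314 genes changed, 108 up and 206 down, with 24 up and 37 down at least 2-fold. With the replicate block the count was 740, which held all 314. A fit of only these 6 libraries called 19 genes and kept 18 of the 314. The 314 rest on a spread shared with the vehicle and FAC libraries, whose deviations were smaller (SD 0.144 to 0.193). The third oleic acid and the third oleic acid + FAC libraries had 0.319 and 0.317. The smaller fit also has fewer libraries to estimate a spread from, so the 2 sources of the lower count cannot be told apart. Of the cholesterol genes 6 rose over all genes and 10 adjusted over the list alone, among them IDI1 (1.12, adjusted p = 0.0138). That list had a median of 0.27 and a camera adjusted p of 1.1e-14, with an adjusted p = 0.0240 with an estimated correlation. Of the immediate-early genes 5 rose over all genes and 6 adjusted over the list alone, among them EGR1 (1.00, adjusted p = 0.0417), KLF6 (0.66, 0.0245), DUSP1 (0.58, 0.0182) and MYC (0.57, 0.0221), with a median of 0.33, a camera adjusted p of 2.9e-05 and an adjusted p = 0.566 with an estimated correlation.

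Oxidative phosphorylation subunits had a median of 0.28 (camera adjusted p = 1.1e-06, and adjusted p = 0.695 with an estimated correlation). The median was 0.10 without the third oleic acid + FAC library (adjusted p = 0.0342), 0.11 with the length trend removed (0.00814) and 0.32 without the third oleic acid and the third oleic acid + FAC libraries (1.7e-14). Camera also passed for ferroptosis markers (-0.28, 0.00421, and adjusted p = 0.107 with an estimated correlation) and targets of the hypoxia-inducible factors (0.13, 0.0434, and adjusted p = 0.566 with an estimated correlation). The last list did not pass without the first (adjusted p = 0.0776) or the third oleic acid (0.0873) or the first oleic acid + FAC library (0.112). Of its genes, BHLHE40, a circadian transcription factor, rose over all genes (1.01, adjusted p = 0.0145). With the replicate block 8 lists passed instead of 5, adding NRF2 targets (adjusted p = 0.0275), ferroptosis suppressors (0.0460) and the lysosome and autophagy list (0.0460). With an estimated correlation, and without the block, these had adjusted p = 0.599, adjusted p = 0.566 and adjusted p = 0.566. An unadjusted p under 0.05 was found for 2285 genes.

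Leaving out 1 library gave 69, 103 and 449 genes without the first, second and the third oleic acid libraries, and 146, 55 and 173 without the first, second and the third oleic acid + FAC libraries. EGR1 passed only without the first oleic acid + FAC library (adjusted p = 0.0244, and 0.0677 to 0.149 elsewhere). IDI1, BHLHE40 and DUSP1 did not pass without the first or second oleic acid or the second oleic acid + FAC library (0.0592 to 0.0698), and KLF6 and MYC did not pass without those or the first oleic acid + FAC library (0.0547 to 0.113). The count was 775 by DESeq2, 282 by limma-voom, 19 from these 6 libraries alone and 807 with the length trend removed.

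The FAC response with oleic acid followed the response without it. Of the 169 genes called without oleic acid and the 314 called with it, 132 were shared, all in the same direction. Independent lists would share 2.00 in the same direction and 1.73 in opposite directions. The slope over the 169 genes was 0.651 (r = 0.859 across genes), and over the 165 of these with a mean log2 CPM of at least 1 it was 0.928 (r = 0.978). Selecting the 314 genes called with oleic acid gave 1.10. Of the 169 genes, 0 had the opposite sign and 0 passed the interaction test adjusted over those genes alone. The interaction called 0 genes over all genes by edgeR, DESeq2 and limma-voom, with 116 at an unadjusted p under 0.05, again fewer than the 710 reached by chance. Across 12408 genes the correlation was 0.693, against 0.0073 in simulated unchanged groups.

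**Figure D3:**
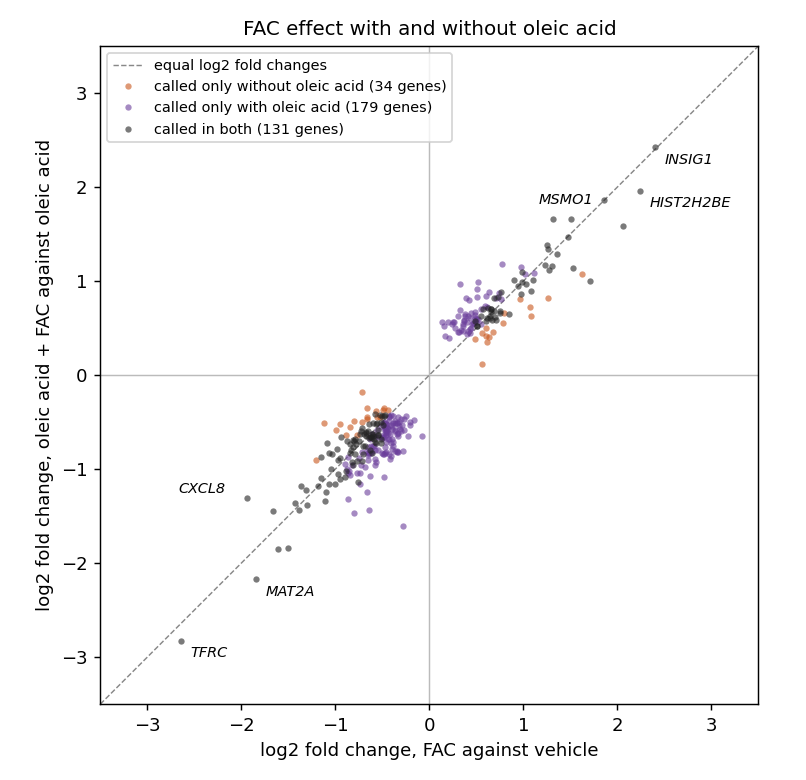
Log2 fold change of oleic acid + FAC against oleic acid (vertical) and of FAC against vehicle (horizontal) for genes with a mean log2 CPM of at least 1, of which 131 were called in both comparisons, 34 only without and 179 only with oleic acid; the dashed line marks equal changes. The genes lie along the line, from TFRC at -2.64 and -2.83 to INSIG1 at 2.40 and 2.42.

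The slope of 0.651 moved with the libraries left out, from 0.521 without the first oleic acid library to 0.948 without the second FAC library. In each of these fits the genes were selected anew. The slopes per replicate number were 0.862, 0.824 and 0.810 (SD 0.027, n = 3). They used differences in log2 CPM (prior count 2) between same-numbered libraries, over the genes selected from all libraries. They are therefore not on the same measure as 0.651, and their SD is not an error of that slope. Camera passed 2 of 26 lists for the interaction, oxidative phosphorylation subunits (median 0.15, adjusted p = 0.00123) and beta-oxidation (0.11, 0.00776), with adjusted p = 0.876 and adjusted p = 0.806 with an estimated correlation. Without the third oleic acid + FAC library the direction of the first turned (adjusted p = 0.809), and it did not pass without the first vehicle (0.259), the first (0.591) or the second oleic acid (0.542) or the second FAC library (0.444). With the replicate block 3 lists passed: these (adjusted p = 7.6e-05 and 0.0217) and, lower, immediate-early genes (0.0399, against 0.0796 without the block; median -0.12; adjusted p = 0.876 with an estimated correlation, without the block). The beta-oxidation list did not pass without the first (0.104) or the third oleic acid (0.0626), the second FAC (0.205) or the second oleic acid + FAC library (0.119).

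**Figure D4:**
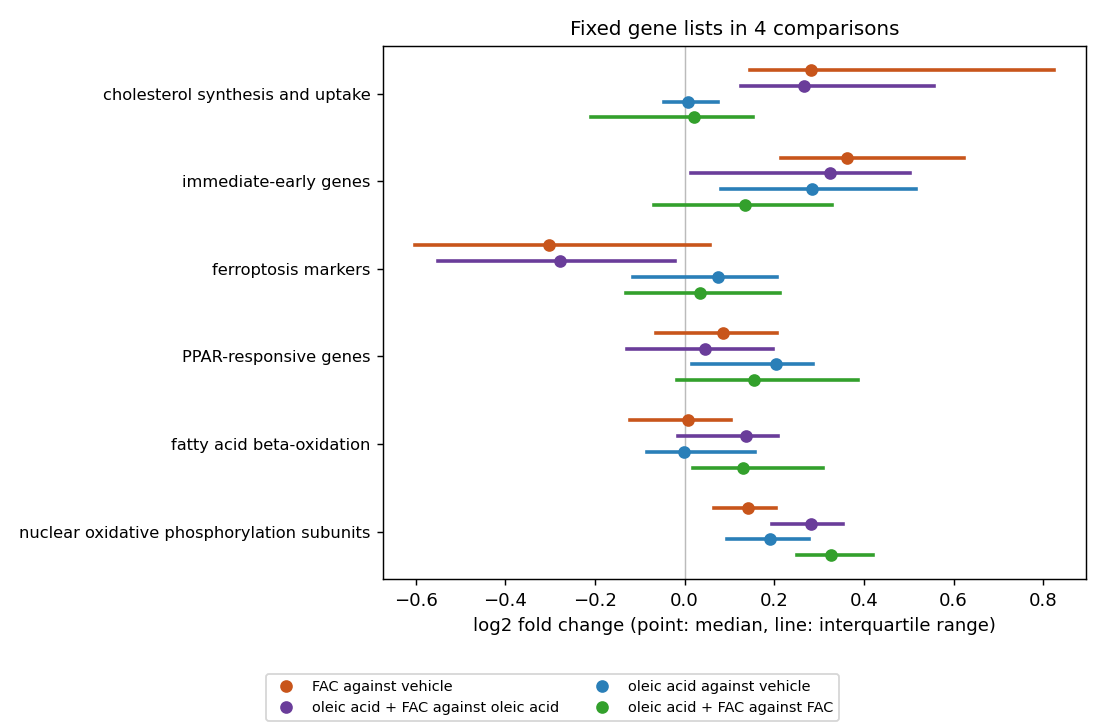
Median (point) and interquartile range (line) of the log2 fold changes of 6 fixed lists in 4 comparisons. Cholesterol genes have medians of 0.28 and 0.27 in the comparisons for FAC, and PPAR-responsive genes 0.20 and 0.15 in those for oleic acid.

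Oleic acid + FAC against vehicle gives the combined treatment. TFRC fell by 3.06 on the log2 scale (SE 0.26, adjusted p = 1.1e-04, n = 3), and falls were also found for MAT2A (-2.33), FAM13B (-1.98) and the chemokine CXCL1 (-1.72, adjusted p = 0.0385). INSIG1 rose by 2.43, FOS by 2.12 (adjusted p = 0.0162), HIST2H2BE by 2.02 and EGR1 by 1.83. PDK4, chosen after its values were seen in this comparison, rose from 5.04 ± 0.77 to 9.57 ± 1.04 CPM (0.93, adjusted p = 0.0321), and ECH1 of beta-oxidation rose by 0.75 (adjusted p = 0.0354). In this comparison 436 genes changed, 146 up and 290 down, with 37 up and 48 down at least 2-fold.

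Of the cholesterol genes 7 rose over all genes and 10 adjusted over the list alone, including MSMO1 (1.68) and IDI1 (1.10), with a median of 0.32, a camera adjusted p of 4.4e-12 and an adjusted p = 0.0423 with an estimated correlation. Of the immediate-early genes 6 rose over all genes and 13 adjusted over the list alone, including KLF6 (0.69) and KLF10 (0.57), with a median of 0.51, a camera adjusted p of 1.3e-10 and an adjusted p = 0.1401 with an estimated correlation. Of the beta-oxidation genes 1 rose over all genes, and adjusted over the list alone 7 rose and 1 fell (median 0.18, camera adjusted p = 0.0367, and adjusted p = 0.414 with an estimated correlation). Oxidative phosphorylation subunits had a median of 0.50 (camera adjusted p = 4.4e-12, and adjusted p = 0.546 with an estimated correlation), which was 0.28 without the third oleic acid + FAC library (3.8e-07) and 0.10 with the length trend removed (0.00415). Camera also passed for mitochondrially encoded mRNAs (0.80, 0.0309, and adjusted p = 0.689 with an estimated correlation) and ferroptosis markers (-0.19, 0.0143, and adjusted p = 0.1401 with an estimated correlation). With the replicate block 8 lists passed camera instead of 6. The beta-oxidation list did not pass without the first (adjusted p = 0.0539) or the second oleic acid + FAC library (0.0834), the ferroptosis markers not without the first vehicle (0.0581) or the second oleic acid + FAC library (0.0609), and the mitochondrially encoded mRNAs not without the first vehicle (0.174), the second (0.0609) or the third oleic acid + FAC library (0.899).

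The 436 genes became 65 and 62 without the second and the third vehicle libraries, and 76 and 184 without the second and the third oleic acid + FAC libraries. FOS did not pass without the second (adjusted p = 0.0863) or the third vehicle library (0.0608), CXCL1 in none of the 6 fits (0.0547 to 0.172), and ECH1 only without the first oleic acid + FAC library (0.0236, and 0.0660 to 0.178 elsewhere). IDI1 did not pass without the second or the third vehicle or the second oleic acid + FAC library (0.0547 to 0.0800), KLF6 not without any vehicle library or the second oleic acid + FAC library (0.0550 to 0.0854), and KLF10 not without the second or the third vehicle or the second or the third oleic acid + FAC library (0.0520 to 0.0991). The count was 1248 by DESeq2, 410 by limma-voom, 162 from these 6 libraries alone, 704 without the third oleic acid and the third oleic acid + FAC libraries and 1089 with the length trend removed.

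Among 51464 transcripts, FAC changed 4 against vehicle, named here after their values were seen: transcripts of CLK3, a kinase of splicing factors (1.63, adjusted p = 0.00882), INSIG1 (2.56, 0.0107), MAT2A (-2.10, 0.0321) and JMJD4 (-1.54, 0.0427). Oleic acid changed 0 against vehicle in edgeR, the tool run for transcripts, with 1088 at an unadjusted p under 0.05, where 2573 would be reached by chance. The counts were 6 in oleic acid + FAC against oleic acid (4 with the replicate block) and 9 against vehicle (8 with the block). Oleic acid + FAC against FAC changed 1, a coding transcript of CRAMP1 (ENST00000397412.7, adjusted p = 0.0138). It had 0 counts in the 3 oleic acid + FAC libraries and 151 to 377 counts in each of the other 9. Against a floor of 3 counts per library, that is at least 74.3-fold below the mean of the FAC libraries. Another coding transcript of the gene, ENST00000293925.9, measured 31.8 ± 6.91 CPM in FAC and 31.4 ± 10.1 CPM in oleic acid + FAC, without TMM scaling. CRAMP1 as a gene measured 45.1 ± 10.5 and 34.0 ± 7.91 CPM (-0.41, adjusted p = 0.707). Leaving out the third vehicle, the second vehicle or the second FAC library gave 0 transcripts for FAC against vehicle, and leaving out the first FAC, the second oleic acid + FAC or the third oleic acid + FAC library gave 0 for oleic acid + FAC against FAC.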

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

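The tests on oxidative phosphorylation genes in this part, with the length trend removed and without the third oleic acid + FAC library, were chosen after the result was seen.

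Nuclear genes of oxidative phosphorylation stand out because the interaction of oleic acid and FAC passed for them in camera (median 0.15, 55 of 60 genes positive, adjusted p = 0.00123), with an adjusted p = 0.876 with an estimated correlation. Without the third oleic acid + FAC library the direction of this interaction turned and it did not pass. With the length trend removed no list passed for the interaction, and 35 of 40 splits gave as many lists as the real one. In oleic acid + FAC against FAC the median of these genes was 0.33 (interquartile range 0.25 to 0.42), with 56 of 60 genes positive. With the trend with transcript length removed from each library the median was 0.042 (-0.03 to 0.11) and the list no longer passed (adjusted p = 0.154). Its members have a median transcript length of 782 bases, against 2645 for all tested genes. Without the third oleic acid + FAC library it was 0.14 (0.07 to 0.19, adjusted p = 1.0e-05, and adjusted p = 0.979 with an estimated correlation), so most of the rise may come from that library and its excess of short transcripts. A smaller effect of oleic acid on mitochondrial gene expression in cells given FAC stays open, since a trend with length and a change in a group of short transcripts overlap.

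Genes of fatty acid beta-oxidation also passed the interaction test in camera (median 0.11, 23 of 29 genes positive, adjusted p = 0.00776), with an adjusted p = 0.806 with an estimated correlation. That list did not pass with the length trend removed. Nor did it pass without the first or the third oleic acid, the second FAC or the second oleic acid + FAC library. The coding transcript ENST00000397412.7 of CRAMP1 passed the interaction test (adjusted p = 0.0405), with 0 counts in the 3 oleic acid + FAC libraries, but with the replicate block 0 transcripts passed it. For DUSP1, the oleic acid libraries lay below the vehicle mean on the log2 scale (mean -0.08), the first of them barely (63.6 CPM against 63.7), and the oleic acid + FAC libraries above the FAC mean (0.13), a difference of 0.21 on the log2 scale whose interaction test did not pass (adjusted p = 1.00).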

How the results depend on the processing

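Several limits bear on all results. Each group has 3 libraries, and whether the replicate numbers stand for separate cultures is not stated. The counts are kallisto estimates whose assignment uncertainty was not modelled. Where 1 library was left out, its group kept 2. Leaving out the third library of both oleic acid groups, removing the length trend (with or without the replicate block), the slope over genes with a mean log2 CPM of at least 1, and leaving out libraries for transcripts and for genes chosen after their values were seen were chosen after the data were seen; the other alternatives were planned before the data were examined. For the counts and lists that moved below, and for the slope with libraries left out, the cause was not tested.

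The number of changed genes moved with the setting. It was 169 for FAC against vehicle, 314 for oleic acid + FAC against oleic acid and 436 for oleic acid + FAC against vehicle in edgeR. In that order, DESeq2 gave 505, 775 and 1248, the replicate block 431, 740 and 1528, and fits of only the groups compared 351, 19 and 162. Removing the length trend gave 464, 807 and 1089, and removing it with the replicate block 1133, 2013 and 2476. With the third library of both oleic acid groups left out, FAC against vehicle gave 672 and oleic acid + FAC against vehicle 704. With 1 library left out, the counts ran from 27 (the third vehicle) to 79 (the first vehicle), from 55 (the second oleic acid + FAC) to 449 (the third oleic acid), and from 62 (the third vehicle) to 324 (the first oleic acid + FAC). For oleic acid + FAC against FAC, edgeR called 0, DESeq2 called 1 (PLIN2), and 1, a different gene (LPCAT1), was called with the length trend removed and the replicate block.

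Of the named genes, 45 results were past the test, with 630 alternatives: 542 stayed past it in the same direction, 88 no longer passed and 0 turned direction. Another 28 results were not past it, with 392 alternatives: 352 stayed so in the same direction, 10 passed and 30 turned direction. In oleic acid + FAC against FAC, FTH1 was -0.010 and SLC7A11 0.13 with the length trend removed. With the third library of both oleic acid groups left out, SLC7A11 was 0.016 and AIFM2 -0.060. HMOX1 was 0.062 in limma-voom and 0.036 with the replicate block. In oleic acid against vehicle, leaving out the third oleic acid libraries gave FASN 0.13 and ACSL3 0.058, and removing the length trend gave FASN 0.083 and ACSL3 0.0065. With 1 library left out the ranges were -0.25 to 0.12 (AIFM2) and -0.029 to 0.61 (HMOX1) in FAC against vehicle. In oleic acid + FAC against FAC they were -0.064 to 0.46 (SLC40A1), -0.22 to 0.027 (SLC7A11), -0.10 to 0.27 (AIFM2), -0.34 to 0.30 (HMOX1) and -0.25 to 0.37 (PTGS2). In oleic acid against vehicle they were -0.15 to 0.14 (FASN), -0.080 to 0.12 (HMGCS1) and -0.14 to 0.063 (ACSL3).

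Of 26 gene lists, camera passed 4 in FAC against vehicle, 5 in oleic acid against vehicle, 6 in oleic acid + FAC against FAC, 5 in oleic acid + FAC against oleic acid, 6 in oleic acid + FAC against vehicle and 2 for the interaction. With an estimated correlation the numbers were 2, 1, 0, 1, 1 and 0. Fry passed 5, 1, 2, 2, 5 and 0. Other splits of the same libraries passed up to 11, 8, 9, 9, 7 and 10 lists in camera at the preset correlation. With the length trend removed, 3 passed in oleic acid against vehicle and 0 for the interaction. In FAC against vehicle 7 passed with the third oleic acid libraries left out. With the replicate block the numbers, in the order of the 6 comparisons above, were 5, 5, 6, 8, 8 and 3. With 1 library left out the ranges were 4 to 8 (FAC against vehicle), 3 to 6 (oleic acid against vehicle), 4 to 8 (oleic acid + FAC against oleic acid), 3 to 10 (oleic acid + FAC against vehicle) and 0 to 5 (interaction). The adjusted p of the list nuclear oxidative phosphorylation subunits, oleic acid against vehicle, ran from 5.6e-13 to 0.0277 with 1 library left out and was 0.00553 with the third oleic acid libraries left out; in this last setting and without the third oleic acid library alone the list was lower. The adjusted p of the list nuclear oxidative phosphorylation subunits, interaction of oleic acid and FAC, ran from 2.5e-14 to 0.809.

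The slope of the FAC effect with oleic acid on that without, 0.651, was 1.10 over genes selected in oleic acid + FAC against oleic acid, 0.483 over all tested genes, 0.724 with the replicate block and 0.928 over genes with a mean log2 CPM of at least 1. This limit kept 165 of the 169 genes, so a few genes of low level lowered the slope to 0.651. In simulated counts with a slope of 0.5, the slope over all called genes was also too low, at 0.34, and 0.50 with the limit. The value of 0.651 is therefore not read as a weaker FAC effect with oleic acid. With 1 library left out, and the genes selected anew in each fit, the slope without that limit ran from 0.521 to 0.948.

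Transcripts changed numbered 4 in FAC against vehicle, 0 in oleic acid against vehicle, 1 in oleic acid + FAC against FAC, 6 in oleic acid + FAC against oleic acid, 9 in oleic acid + FAC against vehicle and 1 for the interaction. With the third oleic acid libraries left out the numbers were 35, 1, 0, 25, 36 and 0. A filter of at least 1 CPM in at least 3 libraries gave 9 in FAC against vehicle and 25 in oleic acid + FAC against vehicle. The replicate block gave 2 in FAC against vehicle and 4 in oleic acid + FAC against oleic acid. It gave 8 in oleic acid + FAC against vehicle and 0 for the interaction. With 1 library left out the ranges were 0 to 5 (FAC against vehicle), 0 to 10 (oleic acid + FAC against FAC), 2 to 17 (oleic acid + FAC against oleic acid), 3 to 20 (oleic acid + FAC against vehicle) and 0 to 8 (interaction).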

Other observations

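The genes and families in the first paragraphs, and the tests on them, on the third libraries and on the immediate-early genes, were chosen after their values were seen; the counts over other splits were planned.

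FAC changed CLK3, CLK4, SRSF6 and SRSF7, genes of splicing control. CLK3 rose from 23.6 ± 0.47 CPM in vehicle to 65.9 ± 7.67 CPM in FAC (log2 fold change 1.48, adjusted p = 1.8e-04 in edgeR, n = 3) and CLK4 from 9.81 ± 1.31 to 25.2 ± 2.66 CPM (1.36, adjusted p = 6.8e-04), while CLK1 (0.75, adjusted p = 0.0544) and CLK2 (0.32, 0.426) did not pass. These kinases phosphorylate SR proteins, which guide splice site choice. Of 12 SR protein genes 0 rose and 2 fell: SRSF6 from 263 ± 10.97 to 118 ± 4.06 CPM (-1.15, adjusted p = 1.9e-04) and SRSF7 from 231 ± 12.04 to 139 ± 5.04 CPM (-0.73, adjusted p = 0.0252). With oleic acid, FAC changed CLK3 by 1.47, CLK4 by 1.28, SRSF6 by -1.10 and SRSF7 by -0.59, each past the test. CLK3, CLK4 and SRSF6 passed in each fit with 1 library left out, in both comparisons; SRSF7 passed in none without oleic acid (adjusted p from 0.0876 to 0.113) and, with it, only without the third oleic acid + FAC library (0.0236, and 0.0702 to 0.185 elsewhere). These families were picked from the values of their members, so no test of them as sets is used. If this altered splicing broadly, transcripts with retained introns or subject to nonsense-mediated decay might take more counts; their share was 5.16% without and 5.14% with FAC (difference -0.023 points, exact permutation within oleic acid strata, two-sided p = 0.93), and without the third oleic acid and the third oleic acid + FAC library the p was 0.717, so a broad change and none cannot be told apart with these transcript estimates and 6 libraries on each side.

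Of chaperone genes, HSPA8, HSPA2 and DNAJA1 fell with FAC. HSPA8, the constitutive cytosolic chaperone, fell from 1127 ± 109 to 456 ± 67.8 CPM (-1.31, adjusted p = 0.00820 in edgeR, n = 3), HSPA2 from 15.3 ± 4.73 to 6.76 ± 0.85 CPM (-1.18, adjusted p = 0.0252) and the co-chaperone DNAJA1 from 271 ± 20.3 to 139 ± 35.0 CPM (-0.97, adjusted p = 0.0427). HSPA8 did not pass without the third vehicle (adjusted p = 0.0513) or the first FAC library (0.0593), HSPA2 passed only without the third vehicle (0.0309, and 0.0810 to 0.121 elsewhere) and DNAJA1 only without the third FAC library (0.0482, and 0.109 to 0.182 elsewhere). In the fixed list of 18 heat shock proteins 10 were positive (median 0.02, mean -0.19). In the fit without the replicate block that list did not pass in camera (adjusted p = 0.137, and adjusted p = 0.753 with an estimated correlation). Of histone genes, looked at because HIST2H2BE was among the largest rises, 22 of 23 tested were positive both without and with oleic acid (medians 1.13 and 0.98, and 1.14 and 0.99 under relative log expression size factors), and 5 rose in each. Poly-A libraries catch mainly the polyadenylated histone mRNAs, and near-identical copies share reads, so the members are not independent.

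The third oleic acid and the third oleic acid + FAC libraries lay apart, at distances of 0.480 and 0.475 log2 units from the other libraries of their groups, against at most 0.347 for the other 10. With the length trend removed the distances were 0.334 and 0.397, still above the highest other (0.296). On the first component after that removal the third oleic acid + FAC library scored 36.6, and the other 10 scored -16.8 to 10.5. This argues against that trend as the whole source for that library. The third oleic acid library scored 6.87, within the other 10, so for it the measures differ and this stays open. Without mitochondrially encoded mRNAs the distances were 0.492 and 0.492, against at most 0.352. That removal, which used 11494 genes instead of 11330, changed no library by more than 3.82%. The distances of both libraries therefore lie mainly in other genes, which argues against those mRNAs themselves as the source. FAC-treated cells mixed into the third oleic acid library would move all 165 genes by a like share, but the median share was -0.086 (quartiles -0.322 to 0.151), although TFRC alone gave 0.641. What remains may include handling of these cultures or libraries, which no label records, and no biological explanation was tested.

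Immediate-early genes passed camera upward with FAC and with oleic acid when each was compared with vehicle (adjusted p = 0.107 and adjusted p = 0.336 with an estimated correlation), so chance values of the shared vehicle libraries could raise both. For FAC the list also passed against oleic acid, with no vehicle library in the comparison (median 0.33, adjusted p = 2.9e-05), which argues against that source for FAC, although with an estimated correlation the adjusted p was 0.566. For oleic acid the list did not pass against FAC (adjusted p = 0.333), and its median was 0.13 (interquartile range -0.07 to 0.33) against 0.28 in oleic acid against vehicle. The list was already higher with FAC (median 0.36 against vehicle), and a smaller response to oleic acid in such cells would lower its median too. This comparison therefore cannot tell chance in the vehicle libraries from an effect of oleic acid, and both stay open.

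Splits of the same 6 libraries into other groups of 3 were too few, 10 with the real one, for a share under 0.05. For FAC against vehicle the real split gave 169 genes and the highest other 0 (1 of 10 as large), and for oleic acid + FAC against vehicle 436 and 0 (1 of 10). For oleic acid against vehicle the values were 0 and 1 (10 of 10) and for oleic acid + FAC against FAC 0 and 0 (10 of 10), where a real count of 0 is reached by any split. For oleic acid + FAC against oleic acid the real split gave 314 and the highest other 1795 (2 of 10). This last split set the first and the second oleic acid and the first oleic acid + FAC libraries against the other 3, which points to the structure of the third libraries, and the 3 other splits that part all pairs of same-numbered libraries gave at most 0. With the replicate block the real split gave 740, and the other splits were not fitted with it. For the interaction the real count was also 0 and the highest other 0 (40 of 40), which any split reaches, so these splits test nothing there.

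For gene lists the real split and the highest other gave 4 and 11 in FAC against vehicle (8 of 10 as large), 5 and 8 in oleic acid against vehicle (7 of 10) and 6 and 9 in oleic acid + FAC against FAC (6 of 10). They gave 5 and 9 in oleic acid + FAC against oleic acid (5 of 10) and 6 and 7 in oleic acid + FAC against vehicle (7 of 10). With 5 to 8 of 10 splits giving as many, the number of lists past camera did not set the real grouping apart. These splits counted lists and did not compare the adjusted p of any list. For the interaction 35 of 40 splits gave as many as the real 2, up to 10, so chance cannot be excluded. For transcripts the values, in the same order of comparisons, were 4 and 1 (1 of 10), 0 and 1 (10 of 10, fixed by the real count of 0), 1 and 4 (6 of 10), 6 and 66 (3 of 10) and 9 and 0 (1 of 10). Here 10 splits are again too few for a share under 0.05. For the interaction 15 of 30 splits gave as many transcripts as the real 1, up to 34, so chance cannot be excluded.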
